A study of Homo sapiens with 5 samples.

How the data were processed

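The series measured open chromatin by ATAC-seq in NCI-H1693 cells after 48 h with 50 nM PRT3789 or DMSO. Per the labels' protocols and the series' design text, viable cells were cryopreserved, nuclei from thawed cells were tagmented with the Omni-ATAC method, and paired reads of 150 bp were sequenced. Per the design text, reads were processed with nf-core/atacseq 2.0, trimmed with Trim Galore, aligned with Bowtie2 to GRCh38 (patch 14, release 110) and stripped of duplicates with Picard. Narrow peaks were called with MACS2 at a p threshold of 0.00001, merged over all samples with bedtools, annotated to the nearest transcription start with HOMER and counted with featureCounts, per the design text. The deposited values are raw read counts per consensus interval, with no normalization. Whether reads or fragments were counted, and whether read ends were shifted to the Tn5 insertion point, is not given in the sources used here; either would apply alike to all libraries. Because intervals were merged over all samples, a site open in either group has an interval, and counts outside intervals were not used here.

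The table held 81029 non-overlapping intervals of 161 to 4824 bp (median 523 bp) on 24 chromosomes, and none ran past a chromosome end of GRCh38. The smallest gap between neighbours was 2, so coordinates were read as 1-based. Each of the 5 count columns matched the title of 1 sample. Counts in intervals ran from 14754593 to 18218006 per library, and the median count per interval was 52 to 84, which sets the precision of single peaks. In each pair of libraries of one group, counts differed by more than sampling noise (chi-square per peak of 1.20 to 1.53). All were kept as separate replicates, though this check cannot show that they were separate cultures. Counting intervals cover counting error only.

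Intervals were annotated with GENCODE release 44 on GRCh38: the nearest transcription start of any gene, and the feature at the interval's midpoint. The feature may be that of a gene other than the nearest one. Peaks within 1 kb of a start were called promoter, those over 3 kb distal and the rest proximal. The deposited gene symbol was the same as the nearest GENCODE gene for 43.9% of intervals, and for 67.1% of those within 1 kb of a start; 29.1% of deposited symbols were LOC identifiers. Peaks were linked to genes within 100 kb. Consensus sequences of 27 transcription factors and 26 reversed versions as controls were searched on both strands in the central 200 bp, and those with at least 50 distal peaks were tested.

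Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided, no covariate), with Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.0349. The SE of a log2 fold change was its unshrunk estimate over the square root of the F statistic, and log2 fold changes of peaks with few counts depend on edgeR's prior count. Peak classes, sequence groups and 16 gene lists were tested with camera of limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 and also with an estimated correlation, which leaves 3 residual degrees of freedom. The lists covered SWI/SNF subunits, YAP/TEAD targets, AP-1 and TEAD factors, epithelial, mesenchymal, integrin, lung lineage, NRF2, p53, cell cycle, interferon, receptor kinase and housekeeping genes, and markers of neuroendocrine, immune, and endothelial or fibroblast cells. No call among the lists, sequences or the distal class held with an estimated correlation. By fry, which tests whether a list's peaks move on balance one way without comparing them with others, 15 of the 16 lists had an adjusted p under 0.05. Shares of counts were compared by an exact permutation test.

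Peaks were named by a rule set before the data were examined. Among peaks with adjusted p under 0.05, a mean of at least 1 CPM, all PRT3789 libraries on one side of both DMSO libraries, and a protein-coding nearest gene within 100 kb, it took the 12 lower and the 8 higher with the largest fold change, 1 per gene. It also took, whatever their result, the most covered promoter peak of SMARCA2, SMARCA4, KRT80, CCN1, CCN2, FOSL1 and GAPDH, and in each list the peak with the smallest p in each direction. Some of the peaks this rule took are not reported here.

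The edgeR steps were tested on simulated data with the real means and library sizes. Among 79529 simulated peaks with 200 changed, edgeR recovered 6 of 50 at 1.25-fold, 26 of 50 at 1.5-fold, 40 of 50 at 2-fold and 47 of 50 at 4-fold, with 10 false among 129 calls. A list of changed peaks planted in the simulation was found, and 0 of 15 others were called. Simulated peaks varied independently of each other, so this does not test the preset correlation in the real data. With only 200 changed peaks, raised and lowered in equal number, it does not test scaling under broad losses either. A separate simulation in which all called-lower peaks fell gave 14588 false higher calls. Alternatives were DESeq2 1.42.0, other scalings (median-ratio, library size, upper quartile, promoter-peak TMM, loess and GC offsets, span 0.3), other filters and thresholds, a test against a fold of 1.5, a replicate block, leaving out each library, autosomes only, and other windows and links. Scaling on CTCF-site peaks, protein-coding starts or genes only, and the deposited gene symbol were chosen after seeing the data. Scripts for annotation, tests and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.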

Results

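Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in NCI-H1693. This is an established human non-small-cell lung cancer line that is deficient in SMARCA4, per the labels. Cells were exposed for 48 h to 50 nM PRT3789, a selective degrader of SMARCA2, or to the vehicle DMSO. SMARCA2 and SMARCA4 are the alternative ATPases of the SWI/SNF chromatin remodelling complexes, so the comparison asks which sites change in accessibility when the remaining ATPase is targeted. The data analysed comprised 3 PRT3789 libraries (replicates 1, 2 and 3) and 2 DMSO libraries (replicates 2 and 3); a DMSO replicate 1 was not analysed here. Read counts over 81029 consensus intervals summed to 14754593 and 18153104 in the DMSO libraries and to 15539495, 18218006 and 17369806 in the PRT3789 libraries. Libraries of one group correlated at 0.983 to 0.986 (Pearson's r of log2 CPM across intervals, which are not independent replicates), and libraries of different groups at 0.805 to 0.824. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

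Exposure to PRT3789 went with a loss of accessibility at a large part of the peaks, and more losses than gains were of at least 2-fold, by a margin that depended on the scaling. Of 80655 tested peaks, 30679 were lower and 25531 higher in PRT3789 than in DMSO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was seen at 24039 of the lower peaks and at 3355 of the higher peaks; with GC offsets these counts were 19247 and 11598, and with loess offsets 17295 and 10067. The promoter of KRT80, which encodes an epithelial keratin, fell from 129.6 ± 5.49 CPM (SD, n = 2) to 20.4 ± 0.776 CPM (SD, n = 3), and an intronic site 4.29 kb from a transcription start of MMP2, a matrix metalloproteinase gene, fell from 75.3 ± 5.73 to 9.61 ± 1.12 CPM. In the other direction, an intronic site of the translation elongation factor gene EEF1A1 rose from 18.9 ± 1.39 to 88.2 ± 10.9 CPM.

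The balance between lower and higher peaks depended on how the libraries were scaled, since no external standard was added. The 30679 lower and 25531 higher peaks of the TMM scale became 26314 and 40504 with upper quartile factors, 33212 and 16160 with TMM factors from promoter peaks, 26696 and 34612 with GC offsets, and 41470 and 5367 with TMM factors from peaks with a CTCF site, an anchor chosen after seeing the data. These scalings moved the median log2 fold change of all peaks, 0.04 on the TMM scale, by 0.31, -0.13, 0.10 and -0.34 respectively. With scaling factors, changes are to be read relative to that shift. GC offsets are no single shift: under them the peaks called lower on the TMM scale moved by a median of 0.55.

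The SMARCA2 promoter itself remained accessible. Its most covered promoter peak (GRCh38 chr9:2014702-2015483, intronic) had 47.5 ± 2.23 CPM in DMSO (SD, n = 2) and 59.6 ± 2.92 CPM in PRT3789 (SD, n = 3), a log2 fold change of 0.33 ± 0.06 (SE) that turned to -0.02 on the CTCF-site scale. The SMARCA4 promoter (chr19:10960256-10961218) was also higher, by 0.42 ± 0.09 on the log2 scale, with 0.07 on the CTCF-site scale. Accessibility at a promoter is no measure of protein, and loss of the SMARCA2 protein was not measured in these libraries. Across the list of 28 genes for SWI/SNF subunits, 44 of 145 linked peaks were lower and 55 higher, with the same counts when adjusted over the list alone, and 61 were lower and 20 higher on the CTCF-site scale. The peak of this list with the smallest p among the lower ones lay at an annotated start of ARID1B, which encodes a DNA-binding subunit of the complex (chr6:157148519-157149293, coding exon), where accessibility fell by 2.83 ± 0.13 on the log2 scale. The promoter of DPF1 (chr19:38223860-38224778), a subunit of the neuronal form, rose by 0.70 ± 0.06. As a whole this list was not called (limma camera, adjusted p = 0.184), and its median log2 fold change of 0.17, which was -0.17 on the CTCF-site scale, and mean of -0.12 differed in sign.

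Distal sites lost accessibility more often than promoters. Among peaks over 3 kb from an annotated transcription start, 21460 of 47166 (45.5%) were lower and 11695 (24.8%) higher. Among peaks within 1 kb of a start, 5798 of 24867 (23.3%) were lower and 11085 (44.6%) higher. A loss of at least 2-fold was seen at 38.4% of distal and 12.7% of promoter peaks. Peaks in between, called proximal here, were lower at 3421 and higher at 2751 of 8622. Distal peaks held 28.1 ± 0.0958% of all counts in DMSO (SD, n = 2) and 20.7 ± 0.202% in PRT3789 (SD, n = 3), and promoter peaks 65.7 ± 0.143% and 74.0 ± 0.249%. For each share, all PRT3789 libraries lay on one side of the DMSO libraries (two-sided exact permutation p = 0.1, the smallest that the 10 splits of these libraries allow).

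The median log2 fold change was -0.21 for distal and 0.15 for promoter peaks (limma camera of distal peaks against the rest, p = 6.05e-05; p = 0.0508 with an estimated correlation). The distal median was 0.10 with upper quartile factors, 0.13 with loess and 0.11 with GC offsets, and the promoter median was -0.19 on the CTCF-site scale. The difference between the classes varied with peak strength. In the top abundance quintile, 38.7% of distal and 8.63% of promoter peaks were lower, whereas in the middle quintile the shares were 42.2% and 41.4%. From the lowest to the top quintile, the difference in median log2 fold change was -0.48, -0.12, 0.10, 0.09 and -0.14. With offsets that remove trends in abundance or GC content, the distal minus promoter difference of -0.36 became 0.07 and -0.03, and it was no longer called (limma camera p-values of 0.165 and 0.0538). The distal log2 fold changes had 2 modes, at -1.92 and 0.36, as the plot of fold changes by class shows.

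**Figure D1:**
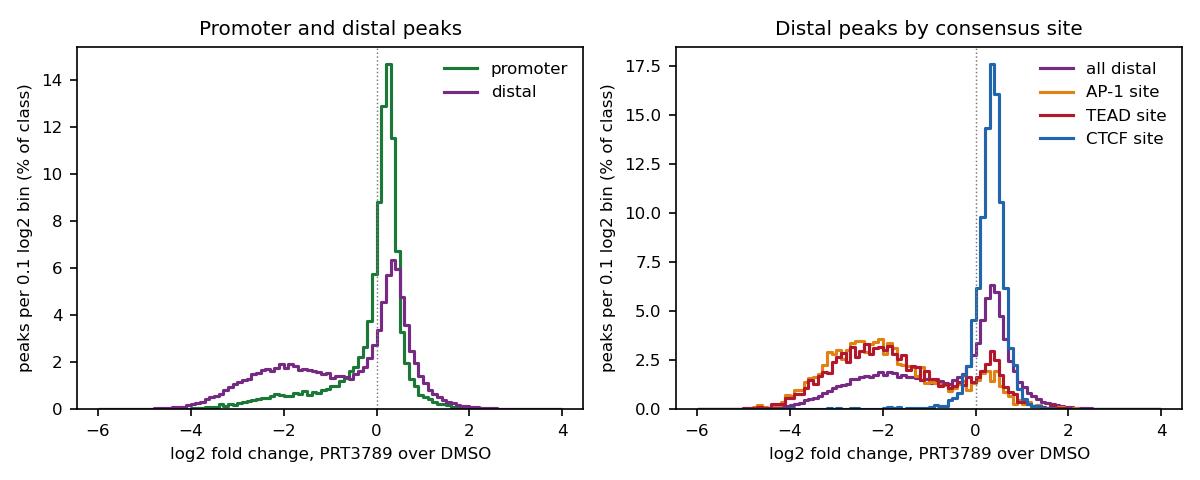
Share of peaks (vertical axis, % of the class per bin of 0.1) by log2 fold change of PRT3789 over DMSO (horizontal axis), for promoter and distal peaks on the left and for distal peaks with an AP-1, TEAD or CTCF consensus site on the right. Distal peaks fall into a group around -1.92 and a group around 0.36, and peaks with AP-1 or TEAD sites lie mostly in the lower group.

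Distal peaks with the recognition sequences of 4 transcription factor families mostly fell, although 14845 of the 21460 lower distal peaks had neither an AP-1 nor a TEAD site. Of 4748 distal peaks with an AP-1 site (FOS and JUN family dimers), 80.9% were lower in PRT3789, against 41.5% of distal peaks without one. Of 4242 with a TEAD site (the DNA-binding partners of YAP and TAZ), 75.7% were lower. Sites for GRHL, the grainyhead-like epithelial factors, were in 1217 distal peaks, of which 69.0% were lower, and RUNX sites in 3153, of which 66.7% were lower. Peaks with a site for CTCF, the insulator protein, stood apart: of 2874, only 2.44% were lower and 51.8% were higher.

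The median log2 fold changes were -2.03 for AP-1, -1.82 for TEAD, -1.74 for GRHL, -1.47 for RUNX and 0.35 for CTCF, and the sign of each held under the 7 other scalings, among which the CTCF median ranged down to 0.00 where these peaks set the scale. With limma's camera and Benjamini-Hochberg adjustment over 19 sequences and 17 reversed controls, the adjusted p was 3.53e-16 for AP-1, 9.63e-11 for TEAD, 7.18e-05 for GRHL, 4.95e-05 for RUNX and 6.52e-14 for CTCF. None of the 17 reversed sequences was called, and the lowest median difference among the reversed versions of AP-1, TEAD, GRHL and RUNX was -0.56, for AP-1; the reversed CTCF sequence was too rare to test. None of the 5 calls held with an estimated correlation, where the adjusted p was 0.663 for AP-1 and TEAD, 0.678 for GRHL and RUNX and 0.118 for CTCF. The other 14 sequences were not called. SP/KLF came closest (390 peaks, median 0.15, adjusted p = 0.0509, limma camera), while sequences for NRF2/MAF (53.9% of 3989 peaks lower), FOX (54.4% of 1903), SOX (51.3% of 3142) and STAT (57.3% of 393) had adjusted p-values of 0.277 to 0.549.

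**Figure D2:**
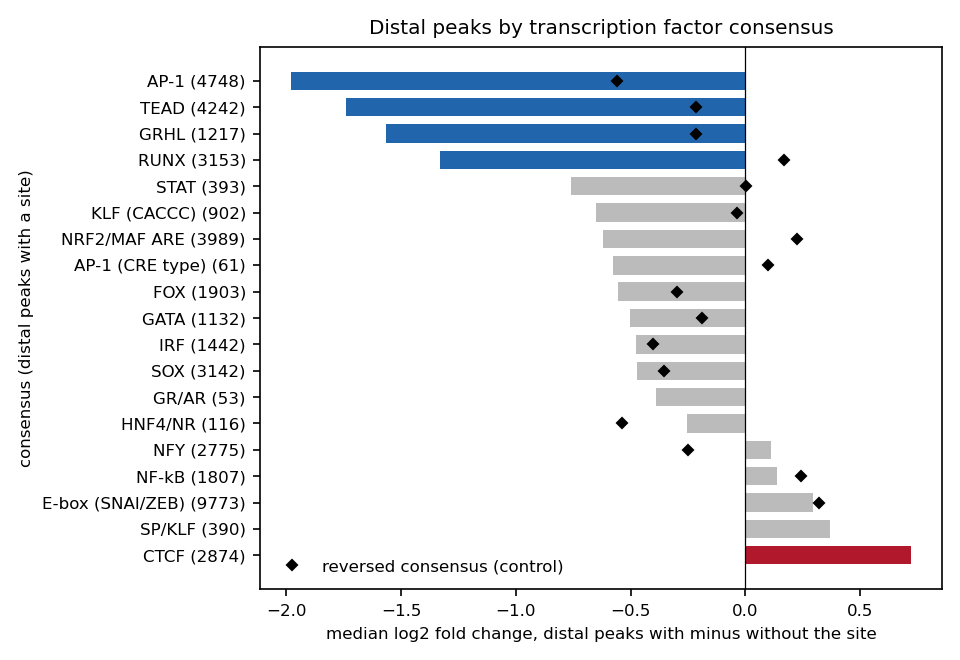
Difference in median log2 fold change (horizontal axis) between distal peaks with and without each transcription factor consensus (vertical axis, number of peaks with a site in brackets); coloured bars passed the limma camera test with the preset correlation, grey bars did not, and diamonds mark the reversed sequence. AP-1 (-1.98), TEAD (-1.74), GRHL (-1.56) and RUNX (-1.33) lie lowest and CTCF (0.72) highest.

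Among peaks linked to genes that respond to YAP and TEAD, more were lower than higher. In this list of 22 genes, fixed before the data were examined, 100 of 183 peaks linked to 21 genes were lower and 36 higher (100 and 37 when adjusted over the list alone). Of all tested peaks 38.0% were lower, and all 21 measured genes of the integrin list, which was not called, had a lower peak. A count of genes therefore does not set a list apart. In the YAP/TEAD list at least 1 lower peak was found at 20 of the genes, of which 14 also had a higher peak. The clearest single loss was a distal intergenic site 53.9 kb from a start of ASAP1, which encodes an Arf GTPase-activating protein (chr8:130497576-130498437), from 38.4 ± 1.17 CPM (SD, n = 2) to 3.53 ± 0.352 CPM (SD, n = 3). Of the 34 peaks linked to ASAP1, 25 were lower, 1 was higher and 8 were not called. The promoter of LATS2, a kinase that restrains YAP (chr13:21059739-21061950), rose by 0.73 ± 0.06 on the log2 scale. The promoter of CCN1 (chr1:85582046-85583501), a matricellular YAP target, was higher by 0.63 ± 0.06. At the promoter of its relative CCN2 (chr6:131949691-131951572) the log2 fold change was -0.28 ± 0.06 (edgeR adjusted p = 6.67e-06), but -0.13 without DMSO replicate 3 (edgeR adjusted p = 0.136) and 0.03 with upper quartile factors.

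The list had a median log2 fold change of -0.68 (limma camera, adjusted p = 0.00833; adjusted p = 0.4998 with an estimated correlation). Of its 125 distal peaks 77 were lower (median -0.83) and of its 35 promoter peaks 10 (median 0.01, adjusted p = 0.579 against other promoters), and the call ended with GC offsets (median -0.16, adjusted p = 0.216) and with links limited to 10 kb (median -0.24, adjusted p = 0.256), all by limma camera. The genes of the AP-1 and TEAD factors themselves were not called as a list (46 of 105 peaks lower and 33 higher, 47 and 33 adjusted over the list alone; limma camera adjusted p = 0.857). Its median of -0.08 was 0.23 with upper quartile factors and 0.01 with GC offsets. The promoter of MAFK, a small MAF protein (chr7:1536742-1538721), fell from 143.3 ± 1.59 to 59.0 ± 2.32 CPM, and an intronic site of YAP1 (chr11:102127277-102127861) rose from 0.463 ± 0.0205 to 4.39 ± 1.13 CPM. The promoter of FOSL1, an AP-1 subunit (chr11:65900112-65900974), had a log2 fold change of 0.06 ± 0.06 (edgeR adjusted p = 0.404), which was 0.37 with upper quartile factors and -0.29 on the CTCF-site scale.

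**Figure D3:**
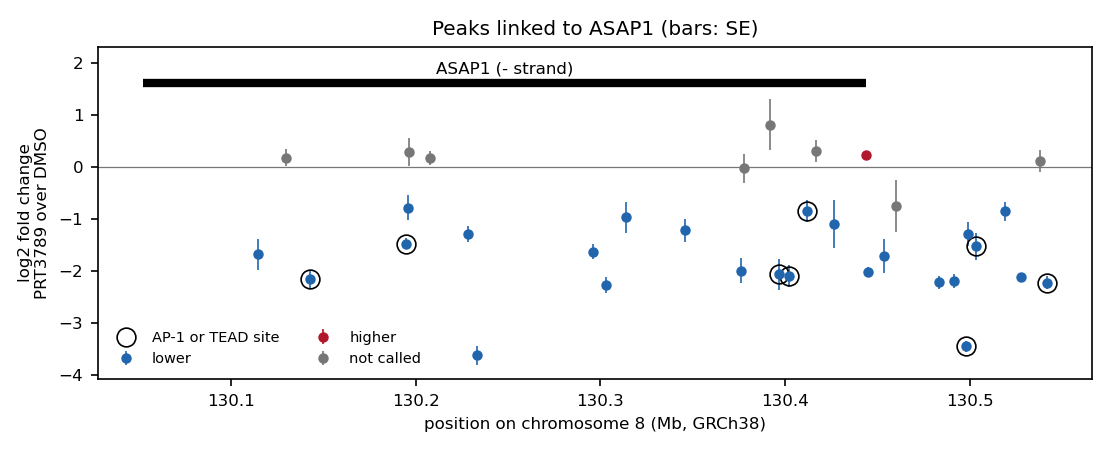
Log2 fold change of PRT3789 over DMSO (vertical axis, bars are SE) of the 34 peaks linked to ASAP1 by position on chromosome 8 (horizontal axis, Mb, GRCh38), coloured blue for lower, red for higher and grey for not called; the thick line marks the gene and open circles mark peaks with an AP-1 or TEAD site. The 25 lower peaks spread over introns and the region upstream of the gene.

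Peaks linked to epithelial junction and identity genes were also more often lower than higher, promoters included. Of 134 peaks linked to the 32 genes of this list, 77 were lower and 24 higher, with the same counts when adjusted over the list alone. The KRT80 promoter (chr12:52191052-52192771, UTR) showed the smallest p of the list, with a log2 fold change of -2.67 ± 0.06 (edgeR adjusted p = 8.40e-118). The promoter of KRT8, a simple-epithelium keratin (chr12:52903307-52904005), rose by 0.88 ± 0.08. The list median was -0.46 (limma camera, adjusted p = 0.00147; adjusted p = 0.372 with an estimated correlation), and it was -0.19 over the 69 promoter peaks and -1.16 over the 52 distal peaks, both called against peaks of their class (limma camera adjusted p = 2.47e-04 and 0.0204).

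Several other lists of cell identity and signalling held deep single losses without being called as groups with the main settings. Among mesenchymal genes, 43 of 87 peaks were lower and 18 higher, with the same counts when adjusted over the list alone (median -0.37, limma camera adjusted p = 0.0711), although the list was called with loess offsets, GC offsets and links to the nearest protein-coding gene (limma camera adjusted p = 0.0469, 0.0489 and 0.0230). These calls rest on the preset correlation; with the main settings the adjusted p was 0.372 with an estimated correlation. The MMP2 site above (chr16:55499588-55501085) fell by 2.97 ± 0.08 on the log2 scale, and the promoter of ZEB2, a repressor of epithelial genes (chr2:144403908-144405100), rose by 1.03 ± 0.07. Among receptor kinase and MAPK feedback genes, 60 of 119 peaks were lower and 38 higher (62 and 39 adjusted over the list alone; median -0.25, and 0.07 with upper quartile factors; limma camera adjusted p = 0.184), and only its promoter peaks were called against their class (limma camera adjusted p = 0.00202). It was called with loess offsets and with links to the nearest protein-coding gene (limma camera adjusted p = 0.0230 and 7.28e-04). All of these calls rest on the preset correlation; with the main settings the adjusted p was 0.662 with an estimated correlation. A promoter of ERBB2, the HER2 receptor (chr17:39705366-39706424, intronic), fell from 115.9 ± 0.681 CPM (SD, n = 2) to 34.9 ± 2.70 CPM (SD, n = 3). An intergenic site 11.6 kb from a start of EGFR (chr7:55212191-55214737) rose from 10.99 ± 0.562 to 27.5 ± 1.92 CPM. Integrin, laminin and hemidesmosome genes had 71 lower and 62 higher of 185 peaks (72 and 62 adjusted over the list alone; adjusted p = 0.938, limma camera). A promoter of the cytolinker gene PLEC (chr8:143939380-143940736) fell by 1.93 ± 0.06 on the log2 scale, and a site near a start of ITGB1 (chr10:32953133-32954321, UTR), the integrin beta-1 gene, rose by 1.34 ± 0.07.

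Interferon response genes moved in both directions, with 20 of 55 peaks lower and 25 higher, the same counts when adjusted over the list alone, and 29 and 11 on the CTCF-site scale (limma camera adjusted p = 0.200), though its 15 distal peaks had a median of 0.72 and were called against other distal peaks (limma camera adjusted p = 0.0204; adjusted p = 0.372 for the whole list with an estimated correlation). Lung epithelial lineage genes had 15 lower and 8 higher of 34 peaks (limma camera adjusted p = 0.857), including a loss of 9.17-fold at an intronic site of ETV5 (chr3:186103955-186104289) and a rise of 1.54-fold at CEBPA (chr19:33302254-33303582). NRF2 target genes had 28 lower and 21 higher of 70 peaks (adjusted p = 0.336). There the loss with the smallest p was intronic in the drug transporter gene ABCC3 (chr17:50638775-50640125, 6.83-fold), and the promoter of GCLC, which encodes the catalytic subunit of glutathione synthesis (chr6:53544316-53545423), rose 1.40-fold. Genes of the p53 response had 13 lower and 21 higher of 49 peaks, but 23 and 4 on the CTCF-site scale (adjusted p = 0.462), with a loss of 4.31-fold in an intron of ZMAT3 (chr3:179037024-179037947). A log2 fold change of 0.31 ± 0.05 at the promoter of RRM2B (chr8:102238547-102239881) turned to -0.03 both with loess offsets and on the CTCF-site scale. In each of these 3 lists the counts adjusted over the list alone were the same.

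Housekeeping and proliferation genes showed the opposite balance on the TMM scale, which turned round on the CTCF-site scale. Of 54 peaks linked to ribosomal protein and housekeeping genes, 31 were higher and 5 lower, and of 63 linked to cell cycle and E2F target genes, 38 were higher and 10 lower, with the same counts when adjusted over the list alone. Their medians were 0.23 and 0.31 (limma camera, adjusted p = 3.81e-04 and 0.00110; adjusted p = 0.372 with an estimated correlation for both). On the CTCF-site scale these medians were -0.11 and -0.04, with 23 lower and 14 higher peaks in the first list and 22 and 13 in the second, so their direction held only relative to other peaks. Neither list was called over its distal peaks only (limma camera adjusted p = 0.0690 and 0.149). The GAPDH promoter (chr12:6533327-6535359) rose by 0.54 ± 0.05 on the log2 scale. The EEF1A1 site (chr6:73513432-73515145) rose by 2.22 ± 0.07, while an intergenic site 8.6 kb from the start of RPL5 (chr1:92822654-92823414) fell by 3.09 ± 0.11. A site near CCND1, the cyclin D1 gene (chr11:69638072-69638575), rose by 0.87 ± 0.09, and an intronic site of E2F2 (chr1:23528170-23528790) fell by 1.62 ± 0.13.

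Lists of other cell types were also included. A culture mixed or misidentified alike in both groups would not move them, so they do not test the identity of the line. None of these was called by limma camera. By fry, the neuronal, immune and endothelial lists moved down (fry adjusted p = 0.0032, 0.0015 and 0.0016). Neuroendocrine and neuronal genes had 19 lower and 17 higher of 51 peaks, immune cell markers 10 and 6 of 23, and endothelial and fibroblast markers 17 and 15 of 47, unchanged when adjusted over the list alone (limma camera adjusted p = 0.858, 0.858 and 0.886). Single peaks in these lists still changed, including an intergenic site near CD3E (chr11:118316474-118317247) that fell 3.12-fold and an intronic site near CDH5 (chr16:66382450-66383651) that fell 6.196-fold. The named higher peaks were near SYP (chrX:49190796-49191816, 1.36-fold), ITGAM (chr16:31333665-31334299, 1.44-fold) and at FAP (chr2:162245460-162246349, 1.45-fold), and those of SYP and ITGAM were not called on the CTCF-site scale (edgeR adjusted p = 0.153 and 0.182). The mean and median log2 fold change differed in sign for all 3 of these lists (medians 0.09, 0.06 and 0.09; means -0.58, -0.59 and -0.48; camera direction down, down and up). They also differed for the p53 and integrin lists (medians 0.07 and 0.03; means -0.24 and -0.30; camera direction up and down). For the lung lineage list the camera direction was up against a median of -0.14 and a mean of -0.40. The medians changed sign under 2 of the 7 other scalings in the lung lineage, NRF2 (median -0.13), p53, integrin, interferon (median 0.14), neuronal, immune and endothelial lists.

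**Figure D4:**
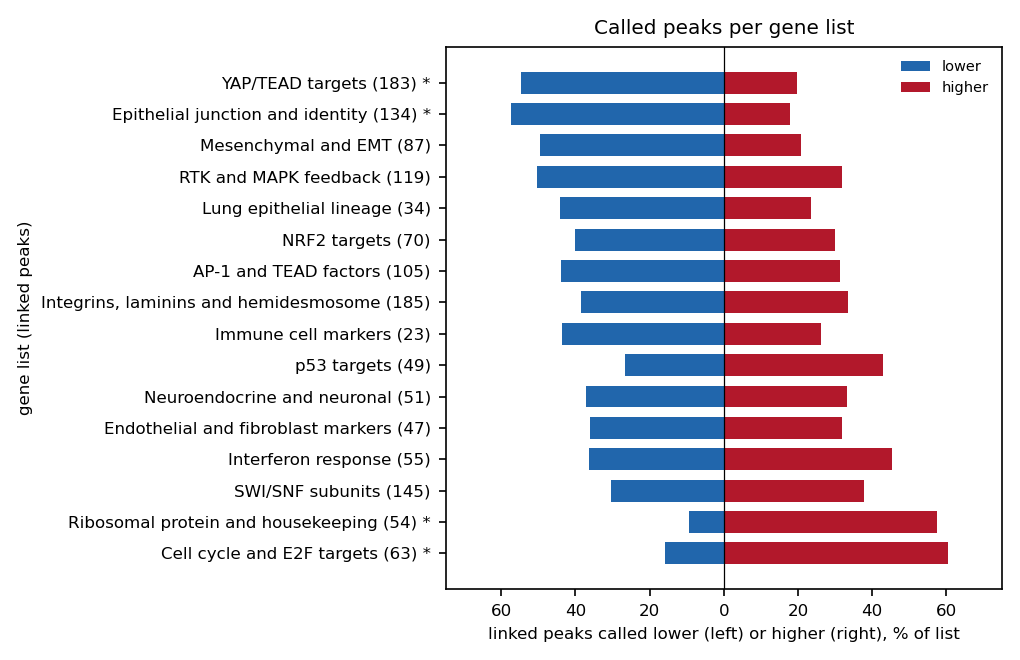
Percentage of linked peaks called lower (bars to the left) or higher (bars to the right) in PRT3789 for each gene list fixed before the data were examined (vertical axis, number of linked peaks in brackets); an asterisk marks lists that passed the limma camera test with the preset correlation. The YAP/TEAD list has 54.6% lower and 19.7% higher, and the ribosomal and housekeeping list 9.26% and 57.4%.

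The largest losses left almost no signal in the treated cells. Among peaks with a mean of at least 1 CPM, separated groups and a protein-coding nearest gene, the largest decrease on the TMM scale lay in an intron of DMD, the dystrophin gene (chrX:31221133-31221512; FTHL17 in the deposited annotation), with 108 counts in the DMSO libraries together and 4 in the PRT3789 libraries. This is a ratio of 0.0234 after scaling (95% exact Clopper-Pearson counting interval 0.00626 to 0.0616). Next among these came an intronic site of PCOLCE2, a procollagen processing enhancer (chr3:142850189-142850712, from 6.66 ± 0.225 to 0.184 ± 0.174 CPM), and an intergenic site near the cadherin gene DCHS2 (chr4:154507062-154507567, from 9.89 ± 0.199 to 0.315 ± 0.275 CPM). Of the other 9 of the 12 named losses, 6 lay in introns, with log2 fold changes of -4.92 ± 0.27 at SH3GL3 (chr15:83475444-83475801), -4.85 ± 0.22 at SIPA1L2 (chr1:232529632-232530222), -4.80 ± 0.27 at CEMIP2 (chr9:71726033-71726261), -4.77 ± 0.18 at CLIC5 (chr6:46062034-46062791), -4.75 ± 0.32 at FHIT (chr3:61181975-61182207) and -4.72 ± 0.36 at SPATA16 (chr3:173113674-173113964). The remaining ones were a coding exon at FFAR4 (chr10:93579084-93579306, -4.80 ± 0.48) and intergenic sites near KRTAP4-8 (chr17:41099770-41099994, -4.94 ± 0.52) and PRPS2 (chrX:12741303-12741886, -4.71 ± 0.27). The order depended on the settings: without PRT3789 replicate 1, PCOLCE2 stood at -6.19 and DMD at -4.80. With loess offsets the order was also different, with CLIC5 at -4.34, SIPA1L2 at -4.16, DMD at -3.25, KRTAP4-8 at -2.91 and FFAR4 at -2.69, and without PRT3789 replicate 2 FFAR4 stood at -6.26. KRTAP4-8 belongs to a cluster of near-identical genes, so its counts are uncertain.

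The largest gains by the same rule rose from a very low level. An intergenic site 5.05 kb from the start of TOB1, an antiproliferative gene (chr17:50860962-50861304), rose from 0.410 ± 0.291 CPM (SD, n = 2) to 6.67 ± 0.945 CPM (SD, n = 3). A site 10.5 kb from a start of the ubiquitin ligase gene TRIM37 (chr17:59117423-59117631, intronic) rose from 0.507 ± 0.234 to 6.93 ± 0.778 CPM. An intronic site near ZNF131 (chr5:43074966-43075769) rose from 2.20 ± 0.173 to 21.2 ± 2.99 CPM. The others of the 8 named gains were near VGLL2, which encodes a TEAD cofactor (chr6:117275412-117275883, intergenic, log2 fold change 3.51 ± 0.39), TUBB6 (chr18:12318291-12318568, intronic, 3.40 ± 0.48), TGIF1 (chr18:3458946-3459700, UTR, 3.30 ± 0.21) and THBS3 (chr1:155205955-155206241, intronic, 3.24 ± 0.15), with the YAP1 site above at 3.24 ± 0.30. With loess offsets the order changed, with TUBB6 at 4.65, VGLL2 at 4.46 and TOB1 at 4.36. Peaks were named by the nearest annotated start, which does not show which gene a site acts on.

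**Figure D5:**
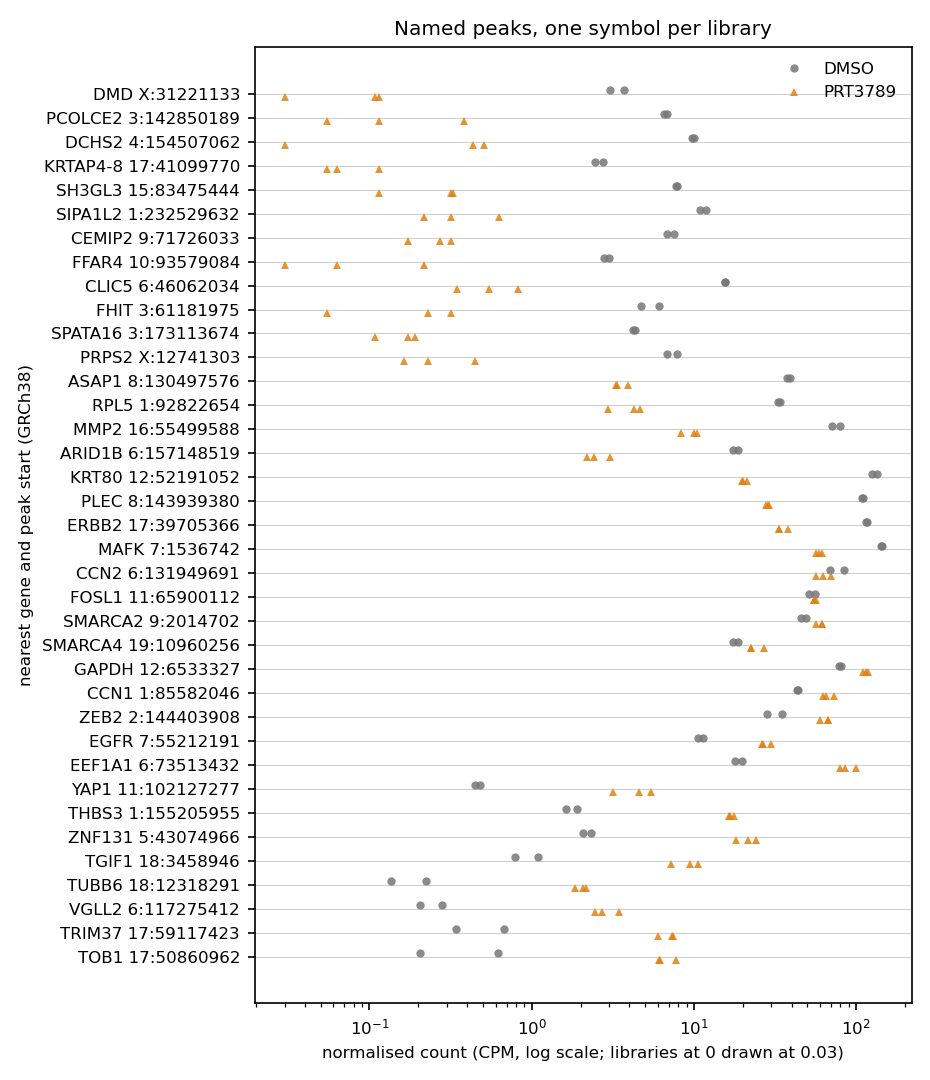
Normalised counts (horizontal axis, CPM on a log scale, with libraries at 0 drawn at the left edge) of named peaks (vertical axis, nearest gene and peak start), with 1 circle per DMSO library (n = 2) and 1 triangle per PRT3789 library (n = 3). The groups do not overlap at any of these peaks except those of CCN2 and FOSL1. Separation was required of the largest changes, and list peaks were taken for small p, so it is no result for them. Of 80655 tested peaks, 63326 were separated in this way.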

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

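Scaling on CTCF-site peaks, protein-coding starts or genes only, and the deposited gene symbol were alternatives chosen after seeing the data. The main counts were 56210 called peaks, 30679 lower and 25531 higher, with 24039 and 3355 at 2-fold or more. Higher peaks numbered 40504 (7722 at 2-fold) with upper quartile factors, 16160 with promoter-peak TMM and 5367 (1397 at 2-fold) with CTCF-site TMM; 2-fold gains numbered 10067 with loess offsets, 11598 with GC offsets and 11920 with the replicate block and GC offsets. The cause was not tested. Restricting the test to the 40514 peaks above the median abundance left 24139 calls, 13396 lower and 10743 higher, 7967 and 466 of them at 2-fold. The smaller number of tested peaks does not alone account for the drop in 2-fold gains: 657 of the 3355 main ones were called higher there. A test against a fold of 1.5 left 27867 calls and 3384 higher, since it excludes small changes. Without 1 library in turn, calls ranged from 47413 to 55650, lower peaks from 28209 to 30400, higher peaks from 19204 to 25250, and the distal minus promoter difference from -0.39 to -0.36; a lone DMSO library was then assumed to vary like the PRT3789 libraries. That difference, -0.36, was 0.0742 with loess offsets, -0.0295 with GC offsets and -0.36 with p = 0.0508 (limma camera) with an estimated correlation. With an estimated correlation 0 of 5 sequences and 0 of 4 lists stayed called. That test has 3 residual degrees of freedom. Its correlations also differed from the preset 0.01: 0.0763 for AP-1, 0.0514 for TEAD and 0.110 for the ribosomal list, but 0.00826 for CTCF. Which of these ended the calls was not tested. A search of the whole peak called 13 sequences and one over all tested peaks 12, where the CRE-type AP-1 difference reversed to 0.12. Log2 fold changes reversed at SMARCA2 (-0.0159), FOSL1 (-0.285) and RRM2B (-0.0295) with CTCF-site TMM, at RRM2B (-0.0339) with loess offsets and at CCN2 (0.0318) with upper quartile factors; the cause was not tested. DESeq2 called 27118 lower and 17054 higher. For named peaks, 1103 comparisons kept direction and call, 16 lost the call, 1 gained it and 5 reversed.

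The replicate numbers 2 and 3 occur in both groups, but same-numbered libraries deviated together only weakly (correlations of 0.02 and 0.02), and nothing in the labels says that a number marks a day or batch. With the replicate number as a block, edgeR called 56637 peaks, 30667 lower and 25970 higher, and kept the calls of the YAP/TEAD list and the distal class (difference -0.38), while the SP/KLF sequence became called (adjusted p = 0.0463, limma camera).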

Other observations

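Tests of the composition of the counts, of scaling, GC content and background for the 2-fold gains, of reversed sequences and of clustering along the genome were chosen after their results had been seen. The peaks with the smallest p-values, chosen here after their values were seen, included the KRT80, MMP2 and EEF1A1 sites of the fixed lists, and the following lay at other genes. Among losses, an intronic site of CLEC16A (GRCh38 chr16:10991490-10992450) had a log2 fold change of -3.82 ± 0.08 (SE), an intronic site of LITAF (chr16:11612046-11612956) one of -3.19 ± 0.07 and an intergenic site near CYP24A1, the vitamin D hydroxylase gene (chr20:54123275-54124216), one of -3.15 ± 0.08. An intergenic site near SDC1, the syndecan-1 gene (chr2:20231412-20233205), had -2.71 ± 0.07. Among gains, an intronic interval at IRF1, an interferon-induced transcription factor (chr5:132477452-132482275), rose from 34.6 to 235.5 CPM and is the widest of all intervals at 4824 bp. The promoter of CA9, a hypoxia-induced carbonic anhydrase (chr9:35680592-35682472), rose from 3.30 to 25.4 CPM, a promoter-class peak at STAT6 (chr12:57095344-57097110) from 4.91 to 31.6 CPM, an intergenic site near ARRDC3 (chr5:91366497-91368768) from 9.62 to 53.2 CPM, a UTR site near CCNG2 (chr4:77167401-77169115) from 2.55 to 22.6 CPM and an intronic site near CITED2 (chr6:139368979-139370618) from 17.4 to 52.3 CPM.

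Some genes lost most of their linked peaks. Among 575 protein-coding genes with at least 10 linked peaks, 21 held more 2-fold losses and 37 more 2-fold gains than expected from the overall share (hypergeometric test, Benjamini-Hochberg adjusted p under 0.05, which treats neighbouring peaks as independent and so overstates the number). The overall share takes no account of class, though 38.4% of distal and 12.7% of promoter peaks lost, and 4.74% and 2.33% gained, at least 2-fold. All 10 peaks linked to ADAMTS18 fell by at least 2-fold, as did 14 of 19 at ME3, 11 of 14 at CTIF, 9 of 11 at IL1RAP, the interleukin-1 receptor accessory protein gene, 10 of 13 at PDLIM1 and 21 of 33 at BCAR3. Gains of at least 2-fold took 15 of 30 peaks at VMP1, 11 of 22 at NPEPPS, 9 of 15 at TRIM37, 7 of 12 at CLTC, the clathrin heavy chain gene, 16 of 51 at EFNA5 and 11 of 25 at MID1. By region, 55 of 300 peaks at 55 to 60 Mb of chromosome 17 and 37 of 152 at 15 to 20 Mb of chromosome 21 gained at least 2-fold, against 4.16% of all tested peaks.

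The first pattern weighed is the group of 22176 peaks higher by less than 2-fold. A drop in the counts of lost peaks alone may lift all others: simulated libraries in which only the called-lower peaks fell gave unchanged peaks a median log2 fold change of 0.19 and 14588 false higher calls. With the scale set on CTCF-site peaks, 11.9% of these peaks stayed called higher, but with the scale set on promoter peaks 58.6% did. Distal CTCF-site peaks had a robust SD of 1.54 in units of their SE around a median of 0.35. This lies between the bound set for a common shift and the one set against it, so it does not decide. A scaling shift and a real small gain cannot be told apart here, since no external standard was added, and an effect of the treatment stays open.

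The second pattern is the group of 3355 peaks higher by 2-fold or more, with a median log2 fold change of 1.29. Under GC offsets 99.6% were still called higher and 3233 were still at 2-fold or more. This cannot decide on a GC trend, since the offsets were fitted to all peaks, lost ones included, and raised the median of these gains to 1.75. More background over whole 5 Mb windows is argued against. For 3287 gained peaks the rise in CPM per kb was compared with peaks lost by 4-fold or more in the same window. At 96.3% it exceeded their median treated density. A scaling shift as the whole cause is argued against, since distal CTCF-site peaks, not chosen for gaining, moved by a median of 0.35 with an upper quartile of 0.494, where these gains need at least 1. A further test, the robust SD of 1.03 of these peaks in units of SE, met the bound first set for a common shift but decides nothing, since choosing peaks by fold narrows it, and it was set aside after its value was seen. A shift may add to the size of these gains, and CTCF-site peaks are assumed to be unaffected. A GC trend, background over shorter stretches and an effect of the treatment stay open.

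A place of the gained peaks near gene ends was weighed as a hypothesis. Outside promoters, 475 of 2775 gained peaks (17.1%) lay within 2 kb of the 3' end of a protein-coding gene, against 4.54% of the other peaks, which is 3.31 times the number expected in strata of chromosome and width (permutation p = 0.0001, the smallest that 10000 permutations can give). Among all gained peaks, promoters included, 3176 had a neighbouring peak within 50 kb. The nearest neighbour was also gained in 844 of these cases, 6.15 times the expected number (permutation p = 0.001, the smallest that 1000 permutations within chromosomes can give). Losses of 2-fold or more clustered as well, with 10201 of 22361 against 6796 expected (permutation p = 0.001). These permutations within chromosomes did not keep promoter and distal peaks apart, so clustering beyond class was not tested. The permutation for gene ends treats neighbouring peaks as independent, so with clustered gains it overstates the evidence. Gains may lie near the ends of transcribed genes, which RNA measurements could test and these data alone do not.

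The third pattern is the deeper fall of distal peaks with AP-1 or TEAD sites. Differences in abundance, GC content or width are argued against by matched strata, in which the difference in median log2 fold change was -1.53 for AP-1 and -1.30 for TEAD, against -1.98 and -1.74 unmatched. Base composition is argued against by the reversed sequences, which gave at most 28.3% of the difference of the true ones. A further hypothesis was that both sites together go with a larger fall. The median was -2.50 in 468 peaks with both, -1.97 with AP-1 alone, -1.72 with TEAD alone and 0.04 with neither. The difference between both and AP-1 alone was -0.53 (permutation p = 0.0001, the smallest that 10000 permutations can give). This permutation treats peaks of the same libraries as independent, so it overstates the evidence. The peaks with both sites were not matched for abundance, GC content or width. These values are consistent with SMARCA2-dependent accessibility at AP-1 and TEAD sites as a hypothesis, while factor binding was not measured and other effects of the compound stay open.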
